A study of Mus musculus with 24 samples.

How the data were processed

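RNA was taken from 12 mouse tumours of the p53-null, triple-negative mammary model 2153L, grown from fragments in the mammary fat pad of female BALB/c mice. Per the labels, 4 treatments were given to 3 tumours each. These were vehicle, ORIN1001 (an inhibitor of the IRE1α ribonuclease, 150 mg/kg by mouth every day), docetaxel (a microtubule-stabilising taxane, 10 mg/kg into the peritoneum every week) and the combination of both. Each tumour gave a pair of libraries. The input library was made from total RNA, and the J2 library from RNA pulled down with J2, an antibody to double-stranded RNA. The labels call the tumours biological replicates and the kit a stranded total RNA kit with ribosomal RNA depletion, for 24 libraries in 8 groups.

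The deposited values are counts, as whole numbers per gene and, in a second table, per transposable element (TE) name. Per the submitters' processing notes, fastp 0.23.2, STAR 2.7.3a, featureCounts 2.0.3 and the mm10 build were used in making these counts, with no role or order given. The strand setting of the counting, the handling of reads that align to several places, and whether reads counted for a TE were also counted for a gene are not given in the sources used here. Genes with a near-identical copy (histones, ribosomal proteins with pseudogenes), overlapping genes and genes with an antisense partner therefore carry uncertain counts, as do TE names with many similar copies. Of 53465 gene rows, 53274 were matched to a symbol by their Ensembl identifier, 50604 of them by its exact version. The TE table has 1146 rows. No row lacked a gene or TE name. Coordinates are from the RefSeq annotation of GRCm38.p6, the assembly also called mm10.

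Depth is the total of counts per library. In M (mega) counts, it ran from 2.54 M to 63.3 M in the gene table and from 0.449 M to 8.14 M in the TE table. Spearman correlations between replicates of a group ran from 0.840 to 0.990. The smallest chi-square per degree of freedom between replicates was 12.6, so no pair looked like 1 library entered under 2 names, which would stand near 1.

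Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 12 input libraries were fitted together with 1 coefficient per treatment, and 17768 genes passed the filter. The comparisons were each treatment against vehicle, the combination against each single drug, any treatment, and the interaction (the combination effect less the sum of both single-drug effects). J2 enrichment was fitted on all 24 libraries with the tumour as a block and 1 J2 coefficient per treatment, over 17338 genes. It gives the log2 ratio of J2 to input within tumours, averaged over treatments, for each treatment, and as its change between treatments. All p-values are two-sided.

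The tumour block follows the labels, which pair each J2 library with its input. After removal of group means, the correlation of an input with the J2 library of the same tumour was above 0.1 in 9 of 12 tumours. Replicate numbers shared across treatments were not used as a block in the input comparisons, since none of 18 pairs of inputs with the same number correlated above 0.1.

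TE names were tested in the same designs on a joint table of genes and TE names, so that they share the scaling of the genes, with adjustment over the TE names alone (1054 tested in the input, 1046 for J2). TE names were also grouped into 14 families by their prefixes. The prefix rule of the DNA transposon family was completed after the names in the file had been seen. The share of each TE class in all counts was compared between J2 and input by an exact sign-flip test over the 12 pairs, whose smallest p is 0.000488. Within 1 treatment the smallest such p is 0.25, and 3 tumours against 3 cannot give an exact permutation p below 0.1.

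A set of 38 gene lists (stress pathways, interferon and antigen presentation, cell division, RNA classes and markers of cell types that such a tumour may hold) was written before the data were examined, as were the main designs, the rule for named genes and the first set of alternatives below. Each list was tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, and again with the correlation estimated from the residuals. Members past the threshold are counted over all genes tested and again adjusted over the list alone.

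Genes are named by a rule. They passed an adjusted p of 0.05, had an average log2 CPM of at least 0 and, for comparisons of groups, did not overlap between the groups, which 3 against 3 libraries give by chance for 10% of unchanged genes. Of these, the 10 largest rises and the 10 largest falls were eligible, leaving out symbols of gene models and pseudogenes. Where none passed, the 3 smallest p-values were taken. Ern1, Xbp1 and Trp53 and up to 4 members of each list with the smallest p were added. For TE names the rule took 5 and 5. A result for any treatment has no single fold change, so its genes were taken by the smallest p. Some eligible genes are not reported here.

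The alternatives of that first set were DESeq2 1.42.0, RLE factors, no low-count filter, fits with or without a block, fits on fewer or more libraries, other scalings of the TE table, each library left out in turn, and estimated correlations. Chosen after the data had been seen were removal of the 23 rows above 1% of any library (8 genes and 15 TE names), limma-voom with a weight for each library, and fits without docetaxel replicate 3, alone or together with combination replicate 2.

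The edgeR steps were tested on simulated counts. For input from combination against vehicle tumours, simulated over 17430 genes, 2 of 67 genes changed 1.5-fold were recovered (2.99%), 15 of 67 changed 2-fold (22.4%) and 49 of 66 changed 4-fold (74.2%), with 8 false calls. For the change of J2 enrichment between the same groups, simulated over 16732 genes, the numbers were 0 of 67, 5 of 67 (7.46%) and 43 of 66 (65.2%), with 3 false calls. Comparisons left unchanged gave 0 calls.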

Results

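The study asked how the ribonuclease activity of IRE1α, a sensor of unfolded protein in the endoplasmic reticulum, bears on double-stranded RNA in tumours. Besides splicing the Xbp1 mRNA, IRE1α cleaves other transcripts, an activity called regulated IRE1-dependent decay (RIDD). Input RNA and J2-bound RNA were sequenced from 3 vehicle, 3 ORIN1001, 3 docetaxel and 3 combination tumours, each a transplant of a p53-null mouse mammary carcinoma in an immune-competent host. Gene counts per input library, in M (mega), were 28.2 to 34.8 M for vehicle, 25.4 to 45.0 M for ORIN1001, 3.27 to 63.3 M for docetaxel and 11.9 to 15.7 M for the combination. The J2 libraries held 12.3 to 14.9, 14.1 to 17.4, 6.69 to 18.7 and 2.54 to 11.04 M gene counts in the same order.

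Library composition differed between groups. Counts at ribosomal RNA loci made up 40.3% ± 17.9 (SD, n = 3) of the gene counts in the combination J2 libraries, against 5.33% ± 1.00 for vehicle, 2.36% ± 1.10 for ORIN1001 and 7.24% ± 8.60 for docetaxel. The input of docetaxel tumour 3 stood apart, with 3.27 M gene counts, 70.5% of them at ribosomal RNA loci, against 0.538% to 3.49% in the other inputs. TE counts made up 13.3% ± 2.24 of gene plus TE counts in vehicle inputs, 13.1% ± 1.89 with ORIN1001, 20.3% ± 16.3 with docetaxel (39.2% in tumour 3) and 23.5% ± 5.28 with the combination.

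**Figure D1:**
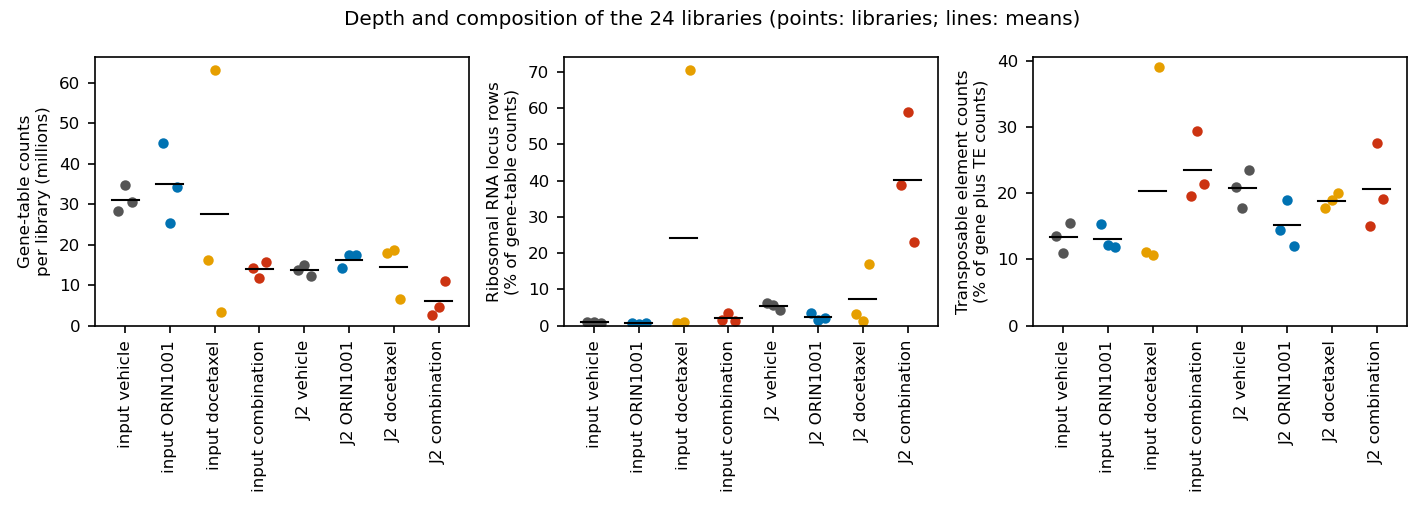
Depth and composition of the 24 libraries by group, with 1 point per library: gene counts in M, and the percent of counts at ribosomal RNA loci and in transposable elements. The input of docetaxel tumour 3 has 3.27 M gene counts and 70.5% at ribosomal RNA loci, and the 3 combination J2 libraries average 40.3% at these loci.

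Trp53 (chromosome 11, 69580348 to 69591873), the gene lost from the tumour model, was counted in every input library. Its mean was 54.6 ± 4.58 CPM (counts per M of gene counts after scaling; SD, n = 3) for vehicle, 43.8 ± 3.79 for ORIN1001, 41.2 ± 4.23 for docetaxel and 30.9 ± 8.26 for the combination. Counts cover the whole gene and include RNA of host cells, so they do not check the null allele. Xbp1 (chromosome 11, 5520641 to 5525993), whose mRNA IRE1α splices, stood at 122 ± 31.7, 144 ± 15.7, 109 ± 35.2 and 64.8 ± 12.8 CPM in the same order. Ern1 (chromosome 11, 106397620 to 106487796), which encodes IRE1α, stood at 45.9 ± 7.05, 45.2 ± 2.16, 36.5 ± 9.14 and 46.9 ± 5.59 CPM. Gene counts do not separate spliced from unspliced Xbp1.

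Gene values from here on are log2 fold changes ± SE from edgeR's quasi-likelihood fit with 3 tumours per treatment, and p-values of genes are Benjamini-Hochberg adjusted. List tests are camera's at its preset correlation. Of all 38 lists over all comparisons, 162 list tests passed at that setting and 0 with an estimated correlation, whose adjusted p is given beside each list.

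The first comparison asked what inhibition of the IRE1α ribonuclease alone changed in the input RNA. Markers of endothelial cells rose as a list, with a median log2 fold change of 0.96 over 10 members (camera adjusted p = 2.4e-11; adjusted p = 0.386 with an estimated correlation). Among them the endothelial cadherin gene Cdh5 stood at 1.35 ± 0.29, Pecam1 at 0.87 ± 0.30 and the VEGF receptor gene Kdr at 0.87 ± 0.31. No member passed over all genes, and 4 passed adjusted over the list alone. Fibroblast markers rose by a median of 1.13 (13 members, adjusted p = 0.000154; adjusted p = 0.476 with an estimated correlation), with 5 members higher and 1 lower adjusted over the list alone.

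The targets of IRE1 and XBP1 in protein folding and secretion fell as a list by 0.22 at the median of 37 members (adjusted p = 5.67e-06; adjusted p = 0.476 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. The chaperone gene Hyou1 (chromosome 9, 44379490 to 44392369) stood at −0.66 ± 0.23 and Dnajb9 at −0.53 ± 0.23. Transcripts reported as RIDD substrates rose as a list, with a median of 0.28 over 10 members (adjusted p = 0.00383; adjusted p = 0.476 with an estimated correlation). None of them passed over all genes and 3 were higher adjusted over the list alone. Of this list Pdgfrb stood at 1.27 ± 0.34, Col6a1 at 1.34 ± 0.45 and Sparc at 0.63 ± 0.22, genes also expressed in stromal cells, whose markers rose too. Interferon-stimulated genes had a median of 0.21 over 40 members and rose as a list (adjusted p = 7.76e-05; adjusted p = 0.801 with an estimated correlation), with 0 members past either threshold. Tubulins fell by 0.44 (12 members, adjusted p = 7.76e-05; adjusted p = 0.476 with an estimated correlation). Markers of cytotoxic and NK cells rose by 0.51 (10 members, adjusted p = 0.000457; adjusted p = 0.476 with an estimated correlation), 3 of them adjusted over the list alone, with the perforin gene Prf1 at 1.91 ± 0.44 and the granzyme gene Gzma at 2.42 ± 0.65. T cell markers fell by 0.35 at the median (13 members, adjusted p = 0.000383) and dendritic cell markers fell by 0.94 (9 members, adjusted p = 0.00402), each with adjusted p = 0.476 with an estimated correlation.

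By edgeR, 0 genes passed for ORIN1001 against vehicle, with 787 at an unadjusted p under 0.05. DESeq2 called 34 (22 higher, 12 lower), limma-voom with sample weights called 2, and 1 gene passed without vehicle 3. The 3 smallest p-values belonged to the protease gene Adamts8 at −2.13 ± 0.36, the pericyte gene Rgs5 at 1.67 ± 0.30 and the receptor gene Calcrl at 1.5 ± 0.29 (edgeR adjusted p = 0.682 for each). Xbp1 stood at 0.24 ± 0.25, Ern1 at −0.02 ± 0.19 and Trp53 at −0.32 ± 0.19 (edgeR adjusted p = 1 for each).

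In the docetaxel inputs, genes of the mitochondrial genome stood above vehicle, and they moved with the library of tumour 3. The 11 mitochondrial mRNAs rose as a list with a median of 2.39 (adjusted p = 0.000836; adjusted p = 0.969 with an estimated correlation) and the 10 mitochondrial rRNA and tRNA genes with one of 2.88 (adjusted p = 0.000317; adjusted p = 0.969 with an estimated correlation). In each list 0 members passed over all genes and 7 were higher adjusted over the list alone. The respiratory chain genes mt-Nd6 and mt-Co1 stood at 7.37 ± 2.08 and 2.93 ± 1.04. Without docetaxel 3 the medians were −0.33 (adjusted p = 0.244) and −0.09 (adjusted p = 0.581), and mt-Nd6 and mt-Co1 stood at −0.65 and −0.32. Targets of IRE1 and XBP1 fell by 0.24 at the median (adjusted p = 0.000104; adjusted p = 0.969 with an estimated correlation), with the chaperone genes Hspa5 at −0.83 ± 0.30 and Hyou1 at −0.72 ± 0.23 and the ERAD gene Derl3 at −1.96 ± 0.57. Without docetaxel 3 that list's median was −0.25 (adjusted p = 0.00246).

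Endothelial markers rose by 0.64 at the median in the same comparison (adjusted p = 0.000104; adjusted p = 0.969 with an estimated correlation), with Emcn at 1.43 ± 0.56 (0.64 and 0.77 without docetaxel 3), and replication-dependent histones by 0.22 (adjusted p = 0.0122; adjusted p = 0.969 with an estimated correlation). Genes of mitosis, the process docetaxel blocks, had a median of 0.10 over 30 members (adjusted p = 0.0703), with the kinase gene Aurkb at 0.38 ± 0.14. Without docetaxel 3 they rose by 0.30 (adjusted p = 1.43e-09; adjusted p = 0.965 with an estimated correlation). Luminal markers did not pass as a list (14 members, adjusted p = 0.503), although 2 members were higher and 1 lower adjusted over the list alone, with the claudin gene Cldn4 at 1.06 ± 0.26.

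No gene passed for docetaxel against vehicle by edgeR, with 1857 at an unadjusted p under 0.05. DESeq2 called 131 (78 higher, 53 lower) and limma-voom 27. The smallest p-values belonged to the claudin gene Cldn8 at 1.57 ± 0.22 (edgeR adjusted p = 0.207), the integrin gene Itga8 at −1.21 ± 0.19 and the matrix gene Fbln2 at −1.48 ± 0.23 (edgeR adjusted p = 0.226 for both). Xbp1 stood at −0.20 ± 0.26, Ern1 at −0.38 ± 0.19 and Trp53 at −0.40 ± 0.20 (edgeR adjusted p = 0.824, 0.52 and 0.507).

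The combination of both drugs gave called genes against vehicle, some of them of antigen presentation. Ciita (chromosome 16, 10480014 to 10531064), the master regulator of MHC class II, rose by 2.49 ± 0.41 (edgeR adjusted p = 0.0312), Nlrc5, its class I counterpart, by 2.22 ± 0.55, the peptide transporter gene Tap1 by 1.64 ± 0.38 and H2-DMa by 1.31 ± 0.30. Of the 17 genes of MHC and antigen presentation, 4 rose over all genes and 12 adjusted over the list alone, with a median of 1.31 (adjusted p = 7.32e-07; adjusted p = 0.744 with an estimated correlation). The T cell chemokine gene Cxcl9 (chromosome 5, 92321331 to 92328079) rose by 3.36 ± 0.59 and Cxcl10 by 1.59 ± 0.33 (edgeR adjusted p = 0.0348 for each). Interferon-stimulated genes rose as a list with a median of 0.39 (adjusted p = 0.00294; adjusted p = 0.877 with an estimated correlation), but 2 of 40 passed, over all genes and adjusted over the list alone.

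Immune cell markers moved in different directions in the combination inputs. Neutrophil markers fell by 2.68 at the median of 9 (adjusted p = 0.00279; adjusted p = 0.744 with an estimated correlation), with the calprotectin genes S100a8 (chromosome 3, 90669071 to 90670034) at −3.53 ± 0.73 and S100a9 at −3.00 ± 0.67 and the surface marker gene Cd177 at −3.91 ± 0.88. Over all genes 2 of them fell, and adjusted over the list alone 6 fell and 1 rose. T cell markers rose by 1.08 (13 members, adjusted p = 0.000615; adjusted p = 0.744 with an estimated correlation), with 0 past the threshold over all genes and 2 adjusted over the list alone. Cd3e stood at 1.94 ± 0.56 and Cd8a at 1.73 ± 0.51 (edgeR adjusted p = 0.0603 and 0.0636). NK and cytotoxic markers rose (median 0.86, adjusted p = 0.00905; adjusted p = 0.744 with an estimated correlation), with the transcription factor gene Tbx21 at 2.03 ± 0.43 and the receptor gene Klrk1 at 2.21 ± 0.54. They were 2 of 10 over all genes and 3 adjusted over the list alone. Dendritic cell markers rose too (median 1.17, adjusted p = 0.00221; adjusted p = 0.744 with an estimated correlation), with Clec9a at 3.25 ± 0.78 and Itgax at 1.22 ± 0.32 as the 2 of 9 that passed, over all genes and adjusted over the list alone.

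Translation and secretion lists fell at the median with both drugs. Cytosolic ribosomal protein genes fell by 0.80 at the median of 81 (adjusted p = 2.94e-20; adjusted p = 0.744 with an estimated correlation), 10 of them over all genes and 49 adjusted over the list alone, with Rps26 at −2.36 ± 0.50, Rpl28 at −1.13 ± 0.26 and Rps19 at −0.80 ± 0.18. Targets of IRE1 and XBP1 fell by 0.43 at the median of 37 (adjusted p = 3.31e-05; adjusted p = 0.744 with an estimated correlation), with Derl3 at −2.26 ± 0.55 as the 1 member past the threshold over all genes, 0 adjusted over the list alone, and Manf at −0.73 ± 0.23. Without docetaxel 3, 14 of them fell over all genes and 14 adjusted over the list alone. Xbp1 stood at −0.91 ± 0.25 (edgeR adjusted p = 0.0563), Ern1 at 0.03 ± 0.19 (edgeR adjusted p = 0.938), and Trp53 fell by 0.82 ± 0.19 (edgeR adjusted p = 0.0433). RIDD substrates had a median of −0.11, with 2 higher and 3 lower adjusted over the list alone, 0 over all genes, and did not pass as a list (adjusted p = 0.937). Genes of hypoxia and glycolysis fell by 0.60 (19 members, adjusted p = 0.000308; adjusted p = 0.762 with an estimated correlation), 1 over all genes and 7 adjusted over the list alone, with the oxygen sensor gene Egln3 at −1.54 ± 0.30 and Pgk1 at −0.92 ± 0.25. Histones fell by 0.68 (65 members, adjusted p = 7.06e-07; adjusted p = 0.841 with an estimated correlation), with 0 members past either threshold. TE counts made up 23.5% on average against 13.3% in vehicle, and ribosomal protein genes took 1.74% ± 0.469 of their gene counts against 2.69% ± 0.161 in vehicle.

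The lists of RNA sensing, inflammasome, p53 targets, inflammatory cytokines and the ATF4 and CHOP stress response did not pass as lists (adjusted p = 0.824, 0.469, 0.797, 0.725 and 0.469). Single members did, over all genes: the DNA sensor gene Aim2 rose by 1.52 ± 0.33, the BH3-only gene Pmaip1 by 1.20 ± 0.30, the cytokine gene Csf1 by 0.75 ± 0.18 and the serine synthesis gene Phgdh by 1.42 ± 0.36. The interferon regulator gene Irf3 fell by 0.59 ± 0.14, the chemokine gene Cxcl1 by 2.01 ± 0.38 and Cebpb by 0.64 ± 0.16. Among the largest changes outside the lists, the secreted glycoprotein gene Scube3 (chromosome 17, 28142100 to 28174851) rose by 3.57 ± 0.54 (edgeR adjusted p = 0.0275), Sectm1b by 3.42 ± 0.77 (5.17 without vehicle 1) and Gbp8, a guanylate-binding protein gene, by 2.72 ± 0.69. The alarmin gene Il33 fell by 5.68 ± 1.42 (1.83 without vehicle 1, adjusted p = 0.17) and the matrix gene Comp by 5.53 ± 1.32. The membrane peptidase gene Mme (chromosome 3, 63295211 to 63383713) fell by 3.56 ± 0.52 and Rps27rt, a copy of a ribosomal protein gene, by 3.06 ± 0.54.

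In all, edgeR called 848 of 17768 genes for the combination against vehicle, 497 higher and 351 lower. With docetaxel 3 kept in the fit, the number rested on single libraries. It was 27, 2 and 0 without vehicle 1, 2 or 3, 1331 without combination 1, 0 without combination 2 and 0 without combination 3, so every gene call above ended in the last 2 of these and without vehicle 3. Without docetaxel 3, which shares only the estimate of spread, it was 5181.

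The combination was also set against docetaxel alone. Among the largest rises were Cxcl9 at 5.23 ± 0.67, the guanylate-binding protein genes Gbp10 at 3.38 ± 0.52 and Gbp4 at 3.01 ± 0.76, the GTPase gene Iigp1 at 3.25 ± 0.73 and the serpin gene Serpina3g at 3.79 ± 0.54 (edgeR adjusted p from 0.0205 to 0.0364). Genes of MHC and antigen presentation rose by 1.38 at the median (adjusted p = 9.28e-09; adjusted p = 0.828 with an estimated correlation), 7 of 17 over all genes and 13 adjusted over the list alone, with Ciita at 2.65 ± 0.44, Tap1 at 1.91 ± 0.39 and Tapbp at 1.10 ± 0.27. Interferon-stimulated genes rose by 0.52 (adjusted p = 0.00013; adjusted p = 0.833 with an estimated correlation), 2 of 40 over all genes and 2 adjusted over the list alone.

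Markers of lymphocytes rose in the same comparison. T cell markers rose by 1.73 (adjusted p = 0.000412; adjusted p = 0.828 with an estimated correlation), 2 of 13 over all genes and 5 adjusted over the list alone, with Cd8a at 2.52 ± 0.58 and Cd3e at 2.58 ± 0.63. NK and cytotoxic markers rose by 2.10 (adjusted p = 0.000592; adjusted p = 0.828 with an estimated correlation), 4 of 10 over all genes and 7 adjusted over the list alone, with Eomes at 2.44 ± 0.60 and Prf1 at 2.17 ± 0.55. Ribosomal protein genes fell by 0.66 (adjusted p = 1.02e-18; adjusted p = 0.828 with an estimated correlation), 16 of 81 over all genes and 35 adjusted over the list alone with 1 higher, with Rpl37 at −1.33 ± 0.30 and Rpl11 at −1.06 ± 0.23. Histones fell by 0.88 (adjusted p = 3.79e-11; adjusted p = 0.828 with an estimated correlation), 11 of 65 over all genes and 14 adjusted over the list alone, with Hist1h2bf at −1.57 ± 0.30 and Hist2h2ab at −3.14 ± 0.78 (−1.36 without docetaxel 3). Mitochondrial mRNAs fell by 3.16 (adjusted p = 0.000107; adjusted p = 0.828 with an estimated correlation), 1 of 11 over all genes, mt-Co3 at −5.28 ± 1.33 (−1.65 without docetaxel 3), and 11 adjusted over the list alone. The median was −0.55 without docetaxel 3 (adjusted p = 0.0496; adjusted p = 0.914 with an estimated correlation). Targets of IRE1 and XBP1 did not pass (median −0.15, adjusted p = 0.404), and Xbp1, Ern1 and Trp53 stood at −0.71 ± 0.26, 0.41 ± 0.20 and −0.42 ± 0.20 (edgeR adjusted p = 0.11, 0.223 and 0.211). The cystine transporter gene Slc7a11 rose by 0.98 ± 0.23, and Cxcl1 and Rps27rt fell by 2.24 ± 0.39 and 3.26 ± 0.56.

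The edgeR count for the combination against docetaxel was 1320 of 17768 genes, 971 higher and 349 lower. The count was 0 without docetaxel 1, docetaxel 2, combination 2 or combination 3, and with only these 6 libraries in the fit, so each call above ended there. It was 4397 without docetaxel 3.

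The combination was then set against ORIN1001 alone. MHC class II and dendritic cell genes rose, with H2-Eb1 at 2.69 ± 0.50, H2-Ab1 at 2.43 ± 0.49, Ciita at 2.17 ± 0.41, the integrin gene Itgax at 2.16 ± 0.33, the plasmacytoid marker gene Siglech at 2.90 ± 0.58 and Clec9a at 3.07 ± 0.77 (edgeR adjusted p from 0.0124 to 0.0312). The antigen presentation list rose by 1.30 (adjusted p = 5.26e-06), 8 of 17 over all genes and 12 adjusted over the list alone, and dendritic cell markers by 2.24 (adjusted p = 0.000228), 4 of 9 and 7 in the same order, each with adjusted p = 0.881 with an estimated correlation. T cell markers rose by 1.76 (adjusted p = 5.57e-06; adjusted p = 0.881 with an estimated correlation), 4 of 13 over all genes and 10 adjusted over the list alone, with Cd8a at 2.58 ± 0.53 and Cd4 at 2.5 ± 0.57.

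Neutrophil and vascular markers were lower than with ORIN1001. Neutrophil markers fell by 3.21 (adjusted p = 0.00366; adjusted p = 0.881 with an estimated correlation), with 5 of 9 lower and 1 higher over all genes, 6 and 1 adjusted over the list alone, S100a8 at −3.68 ± 0.73 and the collagenase gene Mmp8 at −3.33 ± 0.73. Endothelial markers fell by 0.89 (adjusted p = 0.0133; adjusted p = 0.902 with an estimated correlation), 2 of 10 over all genes and 2 adjusted over the list alone, Cdh5 at −1.58 ± 0.29 and Plvap at −1.80 ± 0.44. The resident macrophage genes Vsig4 and Lyve1, the latter also of lymphatic vessels, fell by 4.40 ± 0.86 and 4.23 ± 1.21, the haemoglobin gene Hbb-bs by 4.56 ± 1.21 (2.92 without ORIN1001 tumour 1, adjusted p = 0.0988), the surfactant gene Sftpd by 4.62 ± 0.86, Comp by 4.78 ± 1.31 and Mme by 3.80 ± 0.53. Scube3 rose by 4.27 ± 0.56 (edgeR adjusted p = 0.00801) and the sugar transporter gene Slc2a12 by 4.67 ± 0.91. Xbp1 fell by 1.15 ± 0.25 (edgeR adjusted p = 0.0224), while its target list did not pass (median −0.20, adjusted p = 0.149, with 1 of 37 lower over all genes and 1 adjusted over the list alone). Trp53 and Ern1 stood at −0.50 ± 0.19 and 0.05 ± 0.19 (edgeR adjusted p = 0.0997 and 0.87).

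Ribosomal protein genes fell by 0.78 against ORIN1001 (adjusted p = 1.43e-17; adjusted p = 0.881 with an estimated correlation), 26 of 81 over all genes and 50 adjusted over the list alone, Rps26 at −2.49 ± 0.50. Histones fell by 0.82 (adjusted p = 4.66e-09; adjusted p = 0.902 with an estimated correlation), 5 of 65 by either adjustment over all genes or adjusted over the list alone. Hypoxia genes fell by 0.49 (adjusted p = 0.0037; adjusted p = 0.902 with an estimated correlation), 5 of 19 over all genes and 5 adjusted over the list alone, Egln3 at −1.49 ± 0.30. The edgeR count was 2244 genes, 1279 higher and 965 lower. It was 1254, 211 and 0 without ORIN1001 tumour 1, 2 or 3, 38 without combination 2, 137 without combination 3 and 6507 without docetaxel 3, and no call above held without ORIN1001 tumour 3.

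**Figure D2:**
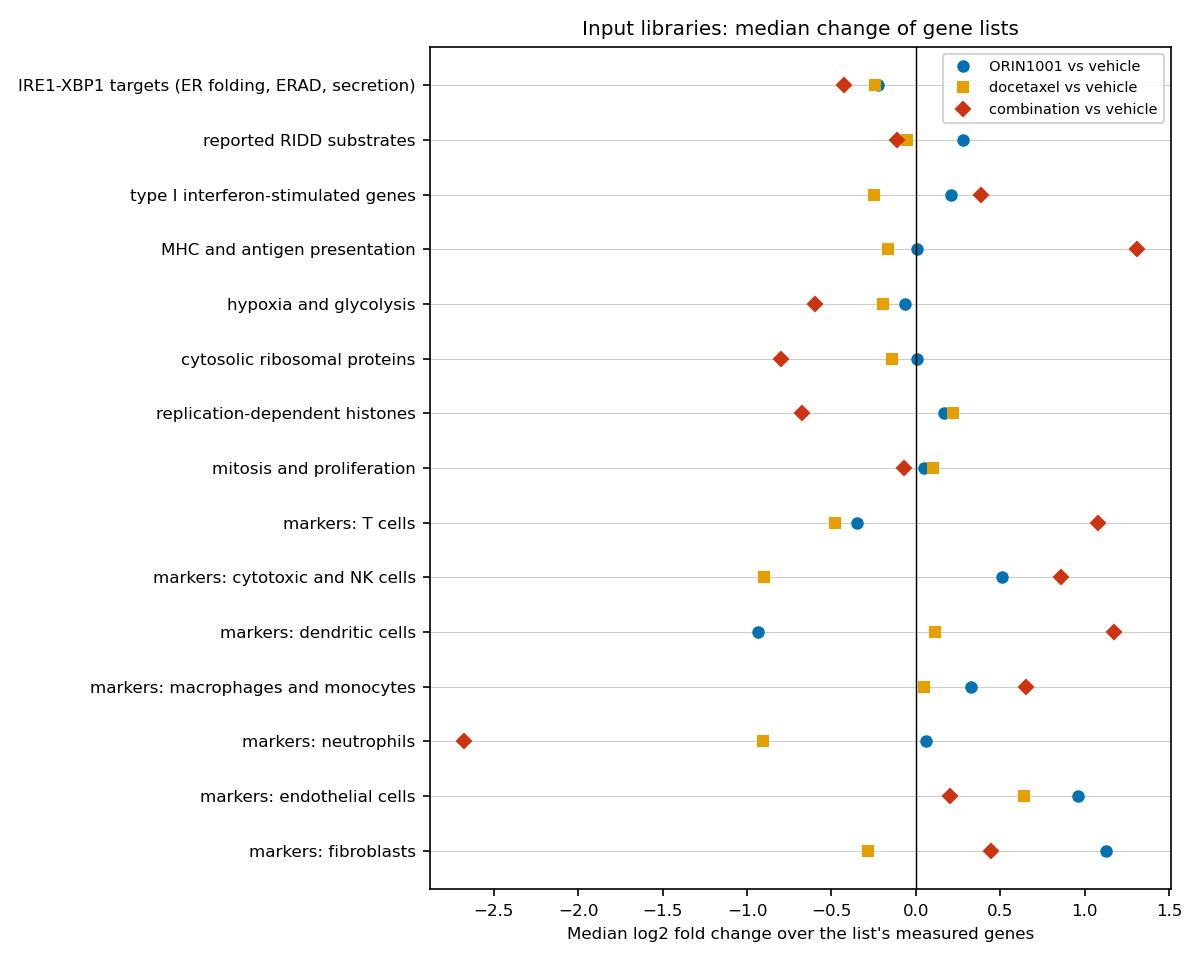
Median log2 fold change of gene lists in the input, with 1 marker per comparison. In the combination against vehicle, antigen presentation stands at 1.31 and T cell markers at 1.08, and ribosomal proteins stand at −0.80 and neutrophil markers at −2.68.

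Whether the combination differed from the sum of the single drugs was tested as an interaction. By edgeR 0 genes passed, with 3134 at an unadjusted p under 0.05; DESeq2 called 771 (564 higher, 207 lower) and limma-voom 3985 (2079 higher, 1906 lower), and 1527 passed without docetaxel 3. The smallest p-values belonged to the long noncoding RNA AU020206 (chromosome 7, 75769038 to 75782120) at 1.86 ± 0.29, Phlda1 at −1.39 ± 0.23 and the microRNA host gene Mir17hg at 2.41 ± 0.42 (edgeR adjusted p = 0.0942 for each). Xbp1 stood at −0.96 ± 0.36 and Trp53 at −0.11 ± 0.27 (edgeR adjusted p = 0.196 and 0.892). As lists, antigen presentation (median 1.24, adjusted p = 4.5e-07; adjusted p = 0.845 with an estimated correlation), T cell markers (2.39, adjusted p = 3.51e-06) and dendritic cell markers (2.14, adjusted p = 0.00061) lay above the sum and endothelial markers below it (−1.63, adjusted p = 2.01e-06), the last 3 with adjusted p = 0.816 with an estimated correlation. Adjusted over the list alone 10, 5, 2 and 7 of their members passed, Cd8a at 3.37 ± 0.77 and Cdh5 at −2.18 ± 0.41 among them, and 0 over all genes. Histones (−1.07, adjusted p = 1.84e-12) and ribosomal proteins (−0.67, adjusted p = 3.72e-14) lay below it, each with adjusted p = 0.845 with an estimated correlation.

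Over the 4 treatments together, 1534 genes differed by edgeR's test of any treatment. The smallest p-values included AU020206, the nitric oxide pathway gene Ddah1 and Itga8 (edgeR adjusted p = 0.0172 for each). The count was 727 without vehicle 1, 285 and 17 without ORIN1001 tumour 2 or 3, 5692 without docetaxel 3, 1 without combination 2 and 0 without combination 3.

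The J2 libraries were compared with their inputs to ask which transcripts the antibody to double-stranded RNA enriched. Averaged over 12 tumours, the microRNA gene Mir5128 (chromosome 2, 37688201 to 37688284) rose by 2.76 ± 0.33, the protocadherin gene Pcdhgb7 by 2.47 ± 0.20, the zinc-finger gene Zfp398 by 2.19 ± 0.18, the NF-kB subunit gene Rel by 2.16 ± 0.17 and the long noncoding RNA Tug1 by 1.92 ± 0.19. S100a9 fell by 3.13 ± 0.19, the histone gene Hist2h2bb by 3.10 ± 0.27, Usmg5, of the ATP synthase, by 3.09 ± 0.18, the translocon gene Sec61g by 2.94 ± 0.18 and the milk protein gene Lalba by 2.78 ± 0.32 (edgeR adjusted p at most 9.62e-06). The Y RNA genes Rny1 and Rny3, structured noncoding RNAs, fell by 6.00 ± 0.33 and 5.19 ± 0.39, in a list of 16 that did not pass (median −0.29, adjusted p = 0.368) and had 2 members higher and 7 lower over all genes and adjusted over the list alone. Xbp1 and Ern1 rose by 0.69 ± 0.18 and 0.50 ± 0.08, and Trp53 fell by 1.05 ± 0.14 (edgeR adjusted p = 0.00443, 7.47e-05 and 2.73e-05).

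Histone mRNAs, which have short bodies and end in a stem-loop, fell by 1.76 at the median of 62 in J2 (adjusted p = 1.44e-20; adjusted p = 0.413 with an estimated correlation), 59 of them over all genes and 60 adjusted over the list alone, Hist1h2ai at −2.83 ± 0.18. Ribosomal protein mRNAs fell by 1.13 (adjusted p = 9.68e-15; adjusted p = 0.413 with an estimated correlation), 62 of 81 over all genes with 3 higher, and 63 with 3 higher adjusted over the list alone, Rpl39 at −2.44 ± 0.17. Mitochondrial mRNAs fell by 2.55 (adjusted p = 0.00109; adjusted p = 0.458 with an estimated correlation), 9 of 10 over all genes and 9 adjusted over the list alone, mt-Nd2 at −3.54 ± 0.44 and mt-Cytb at −2.79 ± 0.39. MicroRNA hairpins rose by 0.97 (73 members, adjusted p = 0.00109; adjusted p = 0.413 with an estimated correlation), 36 higher and 6 lower over all genes and adjusted over the list alone, Mir378a at 2.29 ± 0.25. Targets of IRE1 and XBP1 fell by 0.33 (adjusted p = 0.0221; adjusted p = 0.413 with an estimated correlation), with 7 higher, such as the signal peptidase gene Spcs3 at 1.97 ± 0.21, and 20 lower, such as Sdf2l1 at −1.71 ± 0.14, over all genes, and 8 and 21 adjusted over the list alone. RIDD substrates did not pass as a list (median −0.30, adjusted p = 0.158), with 2 of 10 higher and 6 lower over all genes and adjusted over the list alone. Genes of antigen presentation fell by 0.72 (adjusted p = 0.00622; adjusted p = 0.413 with an estimated correlation), 12 of 17 lower and 2 higher over all genes, 12 and 3 adjusted over the list alone, with B2m at −2.41 ± 0.20. The editing enzyme gene Adarb1 rose by 0.92 ± 0.08. By edgeR 9539 of 17338 genes passed, 4334 higher and 5205 lower.

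Within single treatments, histones had medians of −2.59 in vehicle, −1.70 with ORIN1001, −1.56 with docetaxel and −1.21 with the combination (adjusted p = 5.92e-25, 1.35e-20, 3.45e-18 and 2.67e-06, against adjusted p = 0.238, 0.562, 0.337 and 0.938 with an estimated correlation). Of 62 members 57, 54, 47 and 35 were lower over all genes and 58, 56, 52 and 39 adjusted over the list alone, with 1 higher in the combination. Ribosomal proteins had medians of −1.54, −1.04, −1.28 and −0.60 (adjusted p = 1.54e-16, 6.4e-10, 8.09e-25 and 0.103; adjusted p = 0.238, 0.562 and 0.232 with an estimated correlation for the first 3). Mitochondrial mRNAs had −3.20, −3.71, −4.17 and 0.71 (adjusted p = 0.00572, 0.000877, 2.89e-08 and 0.212; adjusted p = 0.441, 0.562 and 0.337 with an estimated correlation for the first 3). Ribosomal RNA loci took 40.3% of gene counts in the combination J2 libraries, beside these smaller falls. Trp53 stood at −1.61 ± 0.28, −1.45 ± 0.28, −1.08 ± 0.29 and −0.06 ± 0.30 (edgeR adjusted p = 0.000714, 0.00226, 0.0182 and 0.896). The counts of genes were 7172 in vehicle (3510 higher, 3662 lower), 4867 with ORIN1001 (2286 and 2581), 4146 with docetaxel (2074 and 2072) and 6375 with the combination (2825 and 3550). Without 1 tumour of its own group the count was 3669 to 4269 for vehicle and 2108 to 2928 for ORIN1001. It was 496 to 7116 for docetaxel and 3248 without combination 3.

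The change of J2 enrichment from vehicle to combination tumours asked whether both drugs together altered the RNA the antibody bound. Relative to vehicle, the enrichment of mitochondrial mRNAs rose by 3.70 at the median of 10 (adjusted p = 0.000393; adjusted p = 0.643 with an estimated correlation), 7 of them over all genes and 7 adjusted over the list alone, with mt-Co3 at 6.01 ± 1.42 and mt-Co2 at 4.99 ± 1.05. Ribosomal proteins rose by 0.97 (adjusted p = 2.11e-09; adjusted p = 0.643 with an estimated correlation), 31 of 81 over all genes and 41 adjusted over the list alone, Rpl37 at 2.54 ± 0.46 and Rps3 at 1.45 ± 0.28. Histones rose by 1.32 (adjusted p = 4.71e-09; adjusted p = 0.643 with an estimated correlation), 24 of 62 over all genes and 29 adjusted over the list alone, Hist1h2be at 2.81 ± 0.52 and Hist1h1d at 2.41 ± 0.38. Genes of antigen presentation rose by 0.80 (adjusted p = 0.00775; adjusted p = 0.643 with an estimated correlation), 6 of 17 over all genes and 6 adjusted over the list alone, with the immunoproteasome gene Psmb8 at 1.33 ± 0.30. Transcripts reported as RIDD substrates rose by 0.76 (adjusted p = 0.0138; adjusted p = 0.643 with an estimated correlation), 3 of 10 over all genes and 5 adjusted over the list alone, with Col6a1 at 1.89 ± 0.43.

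Some long noncoding RNAs moved the other way in that comparison. The imprinted antisense transcripts Snhg14 (chromosome 7, 59272737 to 60450177) and Kcnq1ot1 fell by 4.99 ± 0.78 and 3.63 ± 0.55, and the nuclear RNAs Malat1 and Neat1 by 1.79 ± 0.45 and 1.64 ± 0.46. The fucosyltransferase gene Fut9 fell by 4.74 ± 0.50, the transporter gene Mfsd4b5 fell by 7.69 ± 2.08 and Slc7a11 by 2.63 ± 0.41. The minor spliceosomal RNA Rnu12 (chromosome 15, 83149645 to 83149794) rose by 5.79 ± 1.11 and Scarna17, of the Cajal body, by 4.85 ± 0.85. Interferon-stimulated genes did not pass as a list (median 0.30, adjusted p = 0.135), with 12 of 40 higher and 3 lower over all genes and 15 and 4 adjusted over the list alone, Bst2 at 2.72 ± 0.46 and Isg15 at 1.65 ± 0.35. The 362 C2H2 zinc-finger genes did not pass either (median −0.33, adjusted p = 0.0828), with 27 higher and 77 lower over all genes, Zfp280d at −2.49 ± 0.35 and Zfp26 at −1.91 ± 0.26. Targets of IRE1 and XBP1 did not pass (median 0.05, adjusted p = 0.91), the stress gene Ddit3 rose by 2.07 ± 0.35 and Trp53 by 1.55 ± 0.41 (edgeR adjusted p = 0.0117), and Xbp1 and Ern1 stood at −0.40 ± 0.49 and −0.14 ± 0.22 (edgeR adjusted p = 0.575 and 0.659). Xbp1 passed in 3 alternatives, from −0.65 to −1.33 (adjusted p from 0.0132 to 0.0242).

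By edgeR 5178 of 17338 genes changed their J2 enrichment from vehicle to the combination, 2208 upward and 2970 downward. The count was 3228, 3250 and 3343 without vehicle 1, 2 or 3 and 3414 without combination 3. Mfsd4b5 lost its call without combination 3, and Neat1 without vehicle 1 or 2. Without combination 2, Trp53 stood at 1.01 and Neat1 at −1.05. With J2 libraries alone Trp53, Fut9 and Malat1 lost their calls (adjusted p = 0.125, 0.0748 and 0.0578), and without the tumour block Isg15, Col6a1, Psmb8, Malat1 and Neat1 did (adjusted p from 0.0511 to 0.134).

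**Figure D3:**
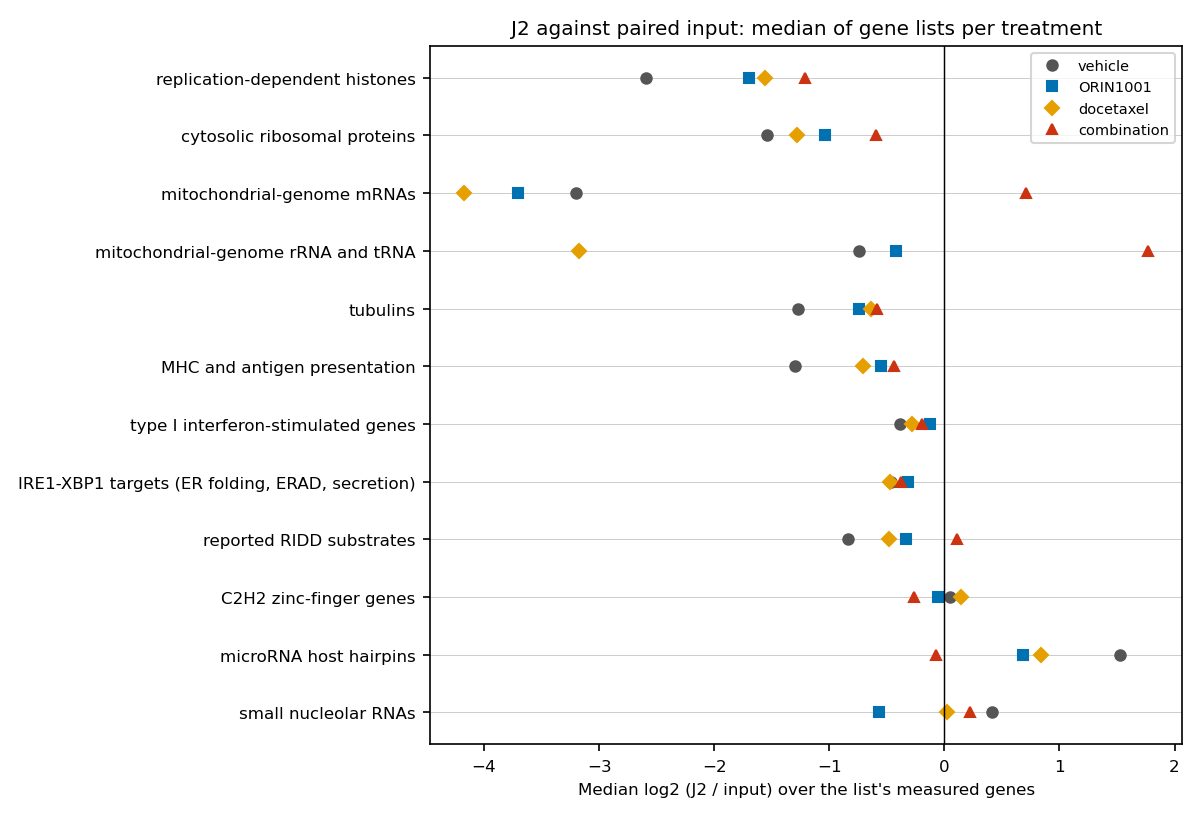
Median log2 ratio of J2 to input for gene lists in each treatment, with 1 marker per treatment. Mitochondrial mRNAs stand at −3.20, −3.71 and −4.17 in vehicle, ORIN1001 and docetaxel tumours and at 0.71 in combination tumours, and histones at −2.59, −1.70, −1.56 and −1.21.

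ORIN1001 alone changed the J2 enrichment of 0 genes by edgeR, with 605 at an unadjusted p under 0.05. DESeq2 called 0, limma-voom with sample weights 3686, and edgeR 3 without ORIN1001 tumour 2. As lists, histones rose by 0.73 (adjusted p = 4.72e-20), ribosomal proteins by 0.46 (adjusted p = 7.69e-14), macrophage markers by 1.16 (adjusted p = 1.32e-12), antigen presentation by 0.40 (adjusted p = 6.56e-07), tubulins by 0.67 (adjusted p = 1.25e-07) and RIDD substrates by 0.32 (adjusted p = 0.00192), each with adjusted p = 0.277 with an estimated correlation. Over all genes 0 members passed, and 9 macrophage markers did adjusted over the list alone. The macrophage gene Adgre1 stood at 1.24 ± 0.29, the class II gene H2-Aa at 1.04 ± 0.27, Tuba1a at 0.96 ± 0.24, Neat1 at −1.28 ± 0.45, Malat1 at −0.98 ± 0.46 and Trp53 at 0.16 ± 0.39 (edgeR adjusted p = 1 for each). With J2 libraries alone H2-Aa and Tuba1a stood at 0.0107 and 0.193.

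Docetaxel alone likewise changed the J2 enrichment of 0 genes by edgeR, with 729 at an unadjusted p under 0.05, 6 by DESeq2, 0 by limma-voom and 10 by edgeR without docetaxel 1. Histones rose as a list by 0.87 (adjusted p = 6.54e-19; adjusted p = 0.553 with an estimated correlation), 2 adjusted over the list alone and 0 over all genes, Hist1h3f at 1.95 ± 0.42. Tubulins, the protein docetaxel binds, rose by 0.72 (adjusted p = 1.01e-05; adjusted p = 0.553 with an estimated correlation), Tuba1a at 0.76 ± 0.25. Mitochondrial mRNAs fell by 1.42 (adjusted p = 0.000532; adjusted p = 0.559 with an estimated correlation), against a median of −0.59 without docetaxel 3 (adjusted p = 0.266). Trp53 stood at 0.53 ± 0.40 (edgeR adjusted p = 0.914).

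From docetaxel to the combination, 5316 genes changed their J2 enrichment by edgeR, 2267 upward and 3049 downward, and 3173 without docetaxel 2. The mitochondrial tRNA gene mt-Te rose by 14.31 ± 2.20 (7.36 without docetaxel 3), mt-Co2 by 5.29 ± 1.05 and Rps27a by 2.45 ± 0.35, while Snhg14 fell by 5.42 ± 0.83 and Fut9 by 4.88 ± 0.54 (edgeR adjusted p from 0.000379 to 0.00227). Trp53 stood at 1.02 ± 0.41 (edgeR adjusted p = 0.075). Mitochondrial mRNAs rose by 5.70 (adjusted p = 7.6e-07; adjusted p = 0.845 with an estimated correlation), 9 of 10 over all genes and 10 adjusted over the list alone, and by 4.94 without docetaxel 3. Ribosomal proteins rose by 0.82 (adjusted p = 7.6e-07; adjusted p = 0.892 with an estimated correlation), 22 of 81 with 1 lower over all genes, and 22 with 1 lower adjusted over the list alone. Over any treatment, 3933 genes changed by edgeR, 6431 without docetaxel 3, 2100 without combination 2 and 1547 without combination 3.

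TE names were examined as a main source of double-stranded RNA in mouse cells. Scaled with the genes, their medians in the input were −0.04 for ORIN1001, 2.39 for docetaxel and 1.09 for the combination against vehicle, and −1.37 for the combination against docetaxel. Scaling on TE counts alone sets the typical TE name near 0 by construction. The TMM factor of docetaxel input 3 was 0.244. The log2 share of all TE counts changed by 0.339, 0.806 and, from docetaxel to the combination, 0.467 (exact permutation p = 0.9, 0.1 and 0.6). Without docetaxel 3 the medians were −0.51 for docetaxel and 1.57 from docetaxel to the combination. In the combination, L1 elements, the active LINE family, rose by 1.14 over 130 names (adjusted p = 3.47e-06), MaLR elements by 1.26 (adjusted p = 8.9e-06), DNA transposons by 1.27 (adjusted p = 2.29e-06) and other endogenous retroviruses by 1.02 over 488 (−0.08 on TE counts alone; adjusted p = 8.53e-08), each with adjusted p = 0.674 with an estimated correlation. Of their members 0 passed over all TE names or adjusted over the list alone. With docetaxel, L1 stood at 2.55 (−0.01 on TE counts alone; adjusted p = 3.11e-17; adjusted p = 0.32 with an estimated correlation), again with 0 members past either threshold.

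Single TE names rarely passed in the input. For the combination against docetaxel 1 name passed by edgeR, the retroviral LTR37-int, which fell by 2.35 ± 0.28 (edgeR adjusted p = 0.00547), with 104 at an unadjusted p under 0.05. Scaling on TE counts alone gave 7 higher and 25 lower, DESeq2 2 and 3, and limma-voom 861 and 15. The count was 917 without docetaxel 3 and 0 without combination 2 or 3, which ended the call. For ORIN1001 against vehicle edgeR gave 0 TE names, 0 of them at an unadjusted p under 0.05, and the other tools 0. For docetaxel it gave 0 (661 at an unadjusted p under 0.05, DESeq2 286, limma-voom 0), but 886, 899 and 1 without docetaxel 1, 2 or 3. Eulor6B stood at 2.21 ± 0.54 and L1M6B at 1.46 ± 0.43 (edgeR adjusted p = 0.0735 for both). For the combination against vehicle it gave 0 (24 at an unadjusted p under 0.05, DESeq2 2, limma-voom 800), 844 without docetaxel 3, and LTR37-int stood at −1.57 ± 0.27 (edgeR adjusted p = 0.147). For any treatment it gave 0 (337 at an unadjusted p under 0.05, DESeq2 208, limma-voom 857), with 1 without vehicle 2 and 729, 759 and 895 without docetaxel 1, 2 or 3.

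J2 enriched single retroviral names over the 12 tumours. RLTR10D rose by 1.74 ± 0.27 and RLTR24B_MM by 1.5 ± 0.28, and LTR37-int fell by 2.07 ± 0.28 (edgeR adjusted p = 0.00477, 0.00885 and 0.00226), among 64 names past the threshold, 46 higher and 18 lower. Scaling on TE counts alone gave 157 higher and 201 lower, the gene-table factors gave 3 and 0, and limma-voom 428 and 92. The median over TE names was −0.06 over all tumours, 0.99 in vehicle, 0.25 with ORIN1001, −0.22 with docetaxel and −1.13 with the combination (0.03, −0.05, −0.10 and −0.33 for the 4 treatments on TE counts alone). The count was 37, 36 and 34 without vehicle 1, 2 or 3, 35 and 33 without ORIN1001 tumour 1 or 2, 42 and 568 without docetaxel 1 or 3, and 36 without combination 3. No family passed over all tumours, L1 standing at −0.24 (adjusted p = 0.996), with 12 higher and 3 lower over all TE names and 13 and 3 adjusted over the list alone.

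In combination tumours 43 TE names passed by edgeR, 37 higher and 6 lower. The retroviral LTRIS4 rose by 4.48 ± 0.45, RLTR10D by 3.94 ± 0.61, the LINE name L1Md_F2 by 3.91 ± 0.70 and the DNA element FordPrefect by 4.66 ± 1.03, while RLTR48B fell by 3.43 ± 0.57 (edgeR adjusted p from 0.000401 to 0.0267). Of 129 L1 names 15 rose over all TE names and 17 adjusted over the list alone, while the family did not pass (median −1.48, adjusted p = 0.479). Scaling on TE counts alone gave 200 higher and 222 lower, the gene table's factors 1 and 0, DESeq2 58 and 105, and limma-voom 122 and 474. The count was 15 without combination 2, 2 without combination 3 and 745 without docetaxel 3. FordPrefect lost its call without combination 1, 2 or 3, and L1Md_F2, RLTR10D and RLTR48B theirs without combination 3.

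No TE name passed by edgeR in vehicle (68 at an unadjusted p under 0.05, DESeq2 9, limma-voom 879), ORIN1001 (29, DESeq2 2, limma-voom 275) or docetaxel tumours (30, DESeq2 4, limma-voom 719). Without docetaxel 3 the counts were 792, 267 and 775. In vehicle, LTRIS4 stood at 2.35 ± 0.42 and the intracisternal A-particle name IAPLTR2_Mm at 2.80 ± 0.49 (edgeR adjusted p = 0.057 for both). MaLR elements rose by 1.35 (0.38 on TE counts alone; adjusted p = 5.77e-06) and MERVL by 1.45 (0.49; adjusted p = 0.0243), each with adjusted p = 0.723 with an estimated correlation, with 0 members past the threshold over all TE names and 0 and 1 adjusted over the list alone.

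The change of J2 enrichment of TE names between treatments was tested last. From docetaxel to the combination 3 names passed by edgeR, with 78 at an unadjusted p under 0.05. LTRIS4 rose by 3.81 ± 0.60 and the major satellite GSAT_MM by 2.88 ± 0.52, and RLTR53B_Mm, outside the rule for names and chosen after its values were seen, fell by 8.38 ± 1.33 (edgeR adjusted p = 0.0379, 0.0464 and 0.0464). The count was 1 without docetaxel 1, 0 without docetaxel 2, 823 without docetaxel 3, 8 without combination 1, and 0 without combination 2 or 3. RLE factors gave 1 higher and 1 lower, as did removal of the most abundant rows, DESeq2 gave 16 and 4, and limma-voom 45 and 682. From vehicle to the combination edgeR gave 0 (197 at an unadjusted p under 0.05, DESeq2 77, limma-voom 814), and 833 without docetaxel 3, with GSAT_MM at 2.63 ± 0.51 and LTRIS4 at 2.13 ± 0.57 (edgeR adjusted p = 0.133 and 0.253). DESeq2 called 13 higher and 64 lower, and scaling on TE counts alone 65 and 59.

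As families, L1 elements fell by 2.02 (adjusted p = 0.00375) and DNA transposons by 2.78 (adjusted p = 7e-08) in J2 enrichment from vehicle to the combination, each with adjusted p = 0.733 with an estimated correlation, against a median of all TE names of −2.02, or −0.24 when scaled on TE counts alone. These are medians over names: the share of all LINE counts in gene plus TE counts changed its log2 J2 to input ratio by 0.000858 and that of DNA transposons by −0.230 (exact permutation p = 1 and 0.8), or by 0.856 and 0.625 within TE counts. L1 made up 8.82%, 39.8% and 20.6% of TE counts in the combination J2 libraries, against 7.83% to 8.79% in vehicle and 39.8% in docetaxel 3. For ORIN1001 the median of all TE names was −0.67 (0.00 on TE counts alone), and L1 fell by 0.81 (adjusted p = 2.3e-08; adjusted p = 0.66 with an estimated correlation). In each case 0 members passed over all TE names and adjusted over the list alone. ORIN1001 changed 0 TE names by edgeR (0 at an unadjusted p under 0.05, DESeq2 0, limma-voom 660) and docetaxel 0 (6 at an unadjusted p under 0.05, DESeq2 0, limma-voom 0, and 1 without docetaxel 3). For any treatment edgeR gave 0 (44 at an unadjusted p under 0.05, DESeq2 18, limma-voom 896), and 826 without docetaxel 3.

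TE classes were also compared by the log2 J2 to input ratio of their share of all counts. For all TE it was 0.200 on average and above 0 in 7 of 12 tumours (exact sign-flip p = 0.236). It was 0.418 for LINE (9 of 12, exact sign-flip p = 0.0522, adjusted 0.157), 0.253 for LTR (8 of 12, exact p = 0.311), 0.599 for DNA transposons (10 of 12, exact p = 0.114) and 0.122 for SINE (7 of 12, exact p = 0.592), or 0.218 (5 of 12), 0.0534, 0.399 and −0.0780 as shares of TE counts. Only TE names outside these classes passed, at −0.774 ± 0.576 (SD, n = 12), below 0 in 12 of 12 tumours (exact sign-flip p = 0.000488, adjusted p = 0.00293). They include the noncoding RNA 7SK, whose weight was not tested. Without docetaxel 3 or combination 1, 2 classes passed. In vehicle the ratio for all TE was 0.644 ± 0.0493 (SD, n = 3) and in the combination −0.211 ± 0.151, where 3 pairs allow no exact p below 0.25.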

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

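Chosen here only after the result was seen were the tests of abundant rows, likeness to docetaxel tumour 3, a wrong label and the treatment. So were the rows and the library left out of the thinning test, whose bound was set beforehand, as were the splits of the tumours. Each result here stands out because the effect of J2 pull-down, or of a drug, differed between treatments by a test of the difference itself.

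For genes these were the change of J2 enrichment over any treatment (3933 genes), from vehicle to the combination (5178) and from docetaxel to the combination (5316). For TE names it was the change from docetaxel to the combination (3). Among gene lists, 10 lay off the sum of the single drugs in the input. Among them were histones (median −1.07) and ribosomal proteins (−0.67), with mitochondrial mRNAs at −3.11, mitochondrial rRNA and tRNA genes at −3.66 (−0.33 and −0.14 without docetaxel 3, adjusted p = 0.309 and 0.94), hypoxia genes at −0.30 and microRNA hairpins at 1.04. In J2 enrichment 14 lists changed with ORIN1001, 12 with docetaxel, 6 with the combination against vehicle and 3 against docetaxel. So did 6, 13 and 5 TE families with the 3 treatments against vehicle, L1 with docetaxel at −0.98 (0.34 without docetaxel 3). With an estimated correlation 0 of these list tests passed.

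For any treatment, 1 of 25 splits of the tumours, the real one, gave 3933 genes and the highest other 0. Chance is thus unlikely. For TE names over any treatment the real count was 0, which all 25 splits reach (highest other 0), so they say nothing on chance. A split of 3 tumours against 3 has 10 forms, too few for a share under 0.05. The real and highest other counts of genes were 0 and 0 with ORIN1001, 0 and 0 with docetaxel, 5178 and 0 with the combination and 5316 and 369 from docetaxel to the combination. For TE names they were 0 and 0 for each of the 3 treatments against vehicle, and 3 and 483 from docetaxel to the combination, where 4 of 10 splits gave 3 or more. A split with 483 names points to a structure of the samples.

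The change of J2 enrichment from vehicle to the combination stood at 5178 genes. Removal of all rows above 1% of a library left 5223, and thinning of all libraries to 1.54 M counts, with those rows and docetaxel tumour 3 left out, left 4585 of 7402, which argues against a few abundant rows or depth as the whole cause. The low-count input of docetaxel tumour 3 had a mean log2 CPM of 5.68 over genes of antigen presentation. The lowest combination one had 7.13 (SD 0.222), which argues against a wrong input label but does not test the J2 one. Alone of 9, the J2 library of docetaxel tumour 3 was nearer the combination mean than its own group (Spearman 0.950, higher by 0.0170). It was as near vehicle (0.949). It held 17.1% at ribosomal RNA loci (combination 23.1% to 58.9%, others at most 6.18%) and L1 as high as the highest combination one. A library difference like theirs thus occurs without ORIN1001. That and the combination treatment stay open and cannot be told apart in the 3 combination tumours.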

How the results depend on the processing

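Fits without docetaxel replicate 3 where it is in neither group, without docetaxel replicate 3 and combination replicate 2 together, with limma-voom sample weights and without the most abundant rows were added after the results had been seen, and so were the tests of these settings. For every value below that moved, the cause was not tested. Of the recomputed counts under the alternatives fixed beforehand, 258 stayed within 1.5 times and 146 did not; under the added ones, 56 stayed and 56 did not. Of single gene, TE and class values under the first set, 2073 kept their side of the threshold, 478 lost the call, 56 gained one and 10, none of them called, changed sign; under the added set these were 681, 9, 56 and 7. No called value reversed. In 3 against 3 libraries the edgeR steps recovered 22.4% of simulated 2-fold changes in the input comparison of combination and vehicle, so smaller changes were mostly out of reach at this depth.

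DESeq2 in place of edgeR gave 3917 genes for any treatment in the input, 34 for ORIN1001, 131 for docetaxel and 2489 for the combination against vehicle, 2246 and 3460 for the combination against docetaxel and ORIN1001, and 771 for the interaction. For the change of J2 enrichment with docetaxel it gave 6. For TE names it gave 208, 286, 2 and 5 in the input (any treatment, docetaxel, combination, combination against docetaxel), 109 in J2 over all tumours, 9, 2, 4 and 163 in vehicle, ORIN1001, docetaxel and combination tumours, and 18, 77 and 20 for the change of enrichment (any treatment, combination against vehicle, combination against docetaxel).

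Limma-voom with sample weights gave 8372, 2, 27, 6901, 5978, 9148 and 3985 genes in the input (any treatment, the 3 treatments against vehicle, combination against docetaxel and ORIN1001, interaction). In J2 it gave 12495, 10326 and 8658 in vehicle, ORIN1001 and docetaxel tumours, and 10710, 3686 and 8518 for the change over any treatment, with ORIN1001 and with the combination. For TE names it gave 857, 800 and 876 in the input (any treatment, combination against vehicle and docetaxel), 520, 879, 275, 719 and 596 in J2 (all tumours, then vehicle to combination), and 896, 660, 814 and 727 for the change (any treatment, ORIN1001, combination against vehicle and docetaxel).

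The replicate block in the input lowered the genes called to 65 for any treatment and to 40, 0 and 717 for the combination against vehicle, docetaxel and ORIN1001. These tumours share only a number: pairs of the same number correlated between −0.196 and 0.0813, and not every tumour correlated best with its own number. Without the tumour block of the J2 fits, the counts of genes became 4489, 2759 and 2181 in vehicle, ORIN1001 and docetaxel tumours and 1829, 2937 and 3183 for the change over any treatment and of the combination against vehicle and docetaxel. TE names became 32 over all tumours, 294 with docetaxel, 7 with the combination and 504 for the change with docetaxel. Neither block moved any other count by over 1.5 times.

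With only the groups compared in the fit, genes in the input were 3124, 0 and 5498 for the combination against vehicle, docetaxel and ORIN1001, and TE names 822 and 0 for the first 2. With all 24 libraries, TE names in the input over any treatment were 444. With J2 libraries alone, the change of the combination against docetaxel gave 3412 genes and 29 TE names, that against vehicle 121 TE names, and any treatment 65.

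With no low-count filter, 17 and 141 genes changed their J2 enrichment with ORIN1001 and docetaxel. TE names were 1 and 604 in the input (any treatment, docetaxel), 106 in J2 over all tumours, 9, 1, 2 and 123 in vehicle, ORIN1001, docetaxel and combination tumours, and 2 and 12 for the change over any treatment and from docetaxel to the combination. RLE factors gave 1 TE name in the input over any treatment. Scaled on TE counts alone, TE names were 32 for the input of the combination against docetaxel, 358 in J2 over all tumours, 39, 20, 37 and 422 in the 4 treatments, and 56, 124 and 136 for the change over any treatment and of the combination against vehicle and docetaxel. With the factors of the gene table they were 77 and 0 in the input (any treatment, combination against docetaxel), 3 and 1 in J2 (all tumours, combination) and 0 for the change from docetaxel to the combination. Removal of the most abundant rows left 23 TE names in J2 of the combination.

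Without docetaxel replicate 3 and combination replicate 2, genes in the input were 2965 (any treatment), 3 (docetaxel), 2043, 2859 and 3739 (combination against vehicle, docetaxel and ORIN1001) and 787 (interaction). In J2 they were 8132 and 8138 with ORIN1001 and docetaxel, and 6099 and 3 for the change over any treatment and with ORIN1001. TE names were 762, 701 and 870 in the input (any treatment, combination against vehicle and docetaxel), 648, 842, 376, 829 and 651 in J2 (all tumours, then vehicle to combination), and 834, 1, 1, 827 and 825 for the change (any treatment, the 3 treatments against vehicle, combination against docetaxel).

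With 1 library left out at a time, docetaxel replicate 3 included for every comparison, gene counts ranged from 0 to 5692 for any treatment in the input, 0 to 1 for ORIN1001, 0 to 5181 for the combination against vehicle, 0 to 4397 against docetaxel, 0 to 6507 against ORIN1001 and 0 to 1527 for the interaction. In J2 they ranged from 3669 to 9228 in vehicle, 2108 to 7175 with ORIN1001, 496 to 7116 with docetaxel and 3248 to 8223 with the combination. For the change they ranged from 1547 to 6431 over any treatment, 0 to 3 with ORIN1001, 0 to 10 with docetaxel, 3228 to 7376 with the combination and 3173 to 7311 from docetaxel to the combination. TE counts in the input ranged from 0 to 895 over any treatment, 0 to 899 with docetaxel, 0 to 844 with the combination and 0 to 917 from docetaxel to it. In J2 they ranged from 33 to 568 over all tumours, 0 to 792 in vehicle, 0 to 267 with ORIN1001, 0 to 775 with docetaxel and 2 to 745 with the combination, and for the change from 0 to 826 over any treatment, 0 to 1 with docetaxel, 0 to 833 with the combination and 0 to 823 from docetaxel to it. TE classes that passed ranged from 1 to 2. The J2 enrichment of genes over all tumours, 8422 to 11016, and the gene list tests, 156 against 162, held within 1.5 times, but 0 list tests passed with an estimated correlation.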

Other observations

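The tests of abundant rows, cell share, composition, treatment and mitochondrial strands in this part were chosen only after the results were seen. So were the rows and library left out of the thinning, whose bound was set beforehand, as were the splits. J2 left behind further groups of protein-coding transcripts over the 12 tumours. Tubulin mRNAs fell by 0.86 at the median of 12 (camera adjusted p = 0.000584; adjusted p = 0.413 with an estimated correlation), 10 of them over all genes and 10 adjusted over the list alone, Tubb2a at −1.32 ± 0.12. Genes of mitosis and proliferation fell by 0.38 (adjusted p = 0.000465; adjusted p = 0.429 with an estimated correlation), 19 of 30 over all genes and 20 adjusted over the list alone, with the replication clamp gene Pcna at −1.41 ± 0.14. Genes of the epithelial-mesenchymal transition fell by 0.63 (adjusted p = 0.00109; adjusted p = 0.413 with an estimated correlation), 13 of 20 over all genes and 14 adjusted over the list alone. Interferon-stimulated genes fell by 0.26 (adjusted p = 0.0219; adjusted p = 0.413 with an estimated correlation), with 19 of 40 lower and 3 higher over all genes and adjusted over the list alone. Small nucleolar RNAs and lipid genes did not pass (adjusted p = 0.794 and 0.947).

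MicroRNA hairpins rose with the combination in the input, by 1.12 against vehicle (59 members, adjusted p = 3.31e-05; adjusted p = 0.744 with an estimated correlation), 3 over all genes and 3 adjusted over the list alone. Against docetaxel they rose by 0.96 (adjusted p = 0.00141; adjusted p = 0.828 with an estimated correlation), 10 over all genes and 17 with 1 lower adjusted over the list alone. Against ORIN1001 they rose by 1.29 (adjusted p = 3.71e-05; adjusted p = 0.881 with an estimated correlation), 8 over all genes and 12 adjusted over the list alone. In J2 against input the same genes had medians of 1.53 in vehicle, 0.68 with ORIN1001, 0.84 with docetaxel and −0.08 with the combination (adjusted p = 4.41e-06, 0.0143, 0.0114 and 0.187; adjusted p = 0.238, 0.562 and 0.477 with an estimated correlation for the first 3).

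The input of combination tumours differed from vehicle at 848 genes. Without rows above 1% of a library 829 passed, and after thinning to 11.3 M counts, with docetaxel tumour 3 left out, 4440 of 5209 passed, so neither a few abundant rows nor depth can be the whole cause. T cell markers stood 3.17 above neutrophil markers (means 1.17 and −2.00, exact permutation over non-independent genes, p = 5.63e-05). A lower tumour cell share alone would not give this but stays open. A shift in RNA composition like that of J2 pull-down may contribute, since across 17038 genes, not independent ones, the change correlated with J2 over input in ORIN1001 tumours (Pearson r = 0.348). The combination treatment stays open and cannot be told apart from it, as both coincide in these 3 tumours; the 1 of 9 other inputs with a TE share as high is docetaxel tumour 3, which decides nothing.

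In J2, mitochondrial genes parted by strand. In vehicle, the 6 genes transcribed from the light strand (mt-Nd6, mt-Tq, mt-Ta, mt-Ty, mt-Te and mt-Tp) had a mean log2 J2 over input of 2.74 ± 1.13 (SD) with 6 of 6 above 0. The 15 from the heavy strand had −3.08 ± 1.61 with 0 of 15 above 0, a difference of 5.81 (exact permutation over non-independent genes, p = 1.84e-05, the smallest it can give). It was 5.19 with ORIN1001 and 4.17 with the combination (exact permutation p = 1.84e-05 for each), where 14 of 15 heavy-strand genes were above 0, and 1.45 with docetaxel (exact permutation p = 0.155), where light-strand genes averaged −2.70 with 1 of 6 above 0. Without tumour 3 these were 4.29, 0.921 and 4 of 6. Row abundance is argued against, since the difference was 5.94 with abundance in the model (permutation p = 1e-04, the smallest the permutations can give). Pairing of transcripts of both mitochondrial strands may explain it, while reads of heavy-strand transcripts counted in the 6 light-strand rows cannot be told apart from it with the strand setting not given.

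By regrouping, chance is unlikely for J2 enrichment of genes over all tumours (1 of 25 splits, real count 9539, highest other 2358). So it is for TE names (1 of 25, 64 and 0) and any treatment in the input (1 of 40, 1534 and 230), all uncorrected. For the interaction (40 of 40, 0 and 6) and TE names over any treatment in the input (40 of 40, 0 and 925) the real count was 0, which every split reaches, so they say nothing on chance. The 10 splits of 3 tumours against 3 are too few for a share under 0.05. Real and highest other counts of genes were 0 and 0 for ORIN1001, 0 and 1 for docetaxel and 848 and 0 for the combination against vehicle. They were 1320 and 299 for it against docetaxel and 2244 and 0 against ORIN1001. For TE names they were 0 and 0, 0 and 911, 0 and 0, and, from docetaxel to the combination, 1 and 932 with 3 of 10 splits at 1 or more. Within 1 treatment only 4 forms exist, again too few, with counts of genes of 7172 and 0 in vehicle, 4867 and 0 with ORIN1001, 4146 and 3553 with docetaxel and 6375 and 0 with the combination. For TE names these were 0 and 0, 0 and 0, 0 and 790, and 43 and 0. The splits with 911, 932, 925 and 790 TE names point to a structure of the samples.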
